A study of Homo sapiens with 3 samples.

How the data were processed

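RNA from 3 biological replicates of untreated NCCIT cells was sequenced. Per the labels' protocols, total RNA was extracted with TRIzol and treated with DNase, libraries were made with a stranded Illumina mRNA kit, and paired-end reads were sequenced on an Illumina NextSeq. Per the submitters' processing notes, HISAT2 2.2.1 and the hg38 build were used. The counting tool, its treatment of reads that map to several places and its use of strand are not given in the sources used here. The labels call the libraries biological replicates and give all 3 the same batch, so no batch could be compared. Tests between libraries measure the spread between these 3 cultures and libraries, and the other tests run across loci.

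The authors deposited 1 table with whole-number counts per row, not normalized, 1 column per library and coordinates for each row. Of its 5491 rows, 5485 are retroviral and 6 are not used in the comparisons: ACTB, GAPDH, PCAT14, HML2.unk_lnc and the 2 rows named HML2_ERVK31_Rec and HML2_ERVK30_Rec. PCAT14 and HML2.unk_lnc overlap proviral rows, and the GAPDH row covers 303.9 kb. Column names matched the library names of the labels. Families were taken from the row names. The 946 rows named HML2.LTR were kept as a class of their own, of which 3 overlap an HML-2 proviral row and 22 overlap any proviral row. The coordinates printed are those of the table, on hg38. Overlap with genes and exons was computed against GENCODE 29 on the same build, where the ACTB row matches an annotated transcript exactly. Of the rows, 8 lie on unplaced or alternate sequences.

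The authors' counts were divided by the column total over all rows to give CPM. Values are means with the SD of 3 libraries. A locus was called detected with at least 10 counts in each library. Shares of counts in 1 library carry 95% Wilson intervals, and a count of 0 was taken to allow up to 3 counts. Both cover counting error only, since reads without molecular identifiers are not independent molecules. Families were compared with 2-sided Fisher's exact tests on detected loci. Human-specific HML-2 proviruses were listed by 12 chromosome bands, from the established HERV-K names K101, K102, K104, K106, K107, K108, K109, K115, K116, K117, K118 and K119, and matched 16 rows. They were compared with the other HML-2 loci by a permutation test of 100000 resamples on log2(mean CPM + 0.5). Each detected locus was tested for equal CPM in the 3 libraries with a chi-square test of homogeneity and Benjamini-Hochberg adjustment at 0.05. This test too sets the libraries against counting error only and treats reads as independent, so a locus called varying differs by more than that error, not by more than cultures usually do. Neighbours in the HML-2 order were called separated when 1 was higher in every library and the mean log2 ratio exceeded its SD. Dispersion came from an intercept-only model in edgeR 4.0.16, with DESeq2 1.42.0 as an alternative. No contrast between groups exists, so no test of differential expression was run. Gene lists set for pluripotency, restriction factors and other cell types, and the locus of ERVMER34-1, were not analysed here.

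Loci were named by a rule that covers the 20 most abundant detected HML-2 proviruses, the 10 most abundant loci of other families, the human-specific list, the first detected locus of each family, the 5 HML-2 and 5 other loci with the lowest adjusted p between libraries, and 3 known envelope loci. This rule, the tests and most alternatives were fixed before the data were examined. The alternatives were floors of 5, 20 and 1 count, a floor on the mean, TMM and DESeq2 scaling, other pseudocounts, counts per kilobase, and each library left out. Which library was lowest at the varying loci was checked under CPM, TMM, DESeq2 and retroviral totals after the result was seen.

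On simulated counts for the 692 detected loci, with 200 loci changed in 1 library, the homogeneity test called 74.0% of loci changed 1.5-fold, 96.0% changed 2-fold, 98.0% changed 3-fold and 1.42% of unchanged loci. These counts were drawn with counting error only, so the rates do not cover spread between replicates. The dispersion fit returned a coefficient of variation of 0.101 for a simulated 0.1 and of 0.309 for a simulated 0.3. Analyses used Python 3.11.15, SciPy 1.17.1 and R 4.3.3.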

Results

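Transcription of endogenous retroviruses was measured by RNA sequencing in 3 biological replicates of untreated NCCIT cells, a human embryonal carcinoma line derived from a non-seminomatous germ cell tumour. The study has 1 group and no control or treated samples, so the question is which loci of the HERV-K HML-2 group are transcribed in these cells, and at what level relative to each other and to the other retroviral families. HML-2 is the youngest HERV-K group in the human genome. The table lists 5485 retroviral rows, of which 4539 are proviral loci of 23 families and 946 are HML-2 long terminal repeat (LTR) entries with a median length of 972 bases. The columns summed to 2177187, 2288601 and 2530825 counts in replicates 1, 2 and 3, and retroviral rows held 72.1%, 79.2% and 77.5% of them. These totals cover the listed rows, and the depth of the whole libraries is unknown. A count of 0 allows a level of up to 1.38, 1.31 and 1.19 CPM (counts scaled to the column total) in the 3 libraries.

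HERV-H took most of the retroviral counts and HML-2 ranked next. HERV-H, a family known for transcription in pluripotent cells, accounted for 86.5% ± 0.396 (SD, n = 3) of retroviral counts, from 486 detected loci of 1186. The 89 HML-2 proviral loci accounted for 9.08% ± 0.379 (SD, n = 3), and 30 of them were detected, which means at least 10 counts in each library. HERV-9 followed with 2.90% ± 0.143 (SD, n = 3) from 17 detected loci of 360, and the HML-2 LTR entries held 0.698% ± 0.0799 (SD, n = 3). Every other family held under 0.2% each, and 692 retroviral rows were detected in all. The HML-2 share was 9.49% in replicate 1 (95% Wilson interval 9.45 to 9.54), 8.75% in replicate 2 (8.71 to 8.79) and 8.98% in replicate 3 (8.94 to 9.02). The spread between libraries was therefore wider than these intervals, which cover counting error only. The share was 5.66% ± 0.230 (SD, n = 3) when counts were divided by locus length, and 5.37% ± 0.211 (SD, n = 3) without the first-ranked provirus.

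**Figure D1:**
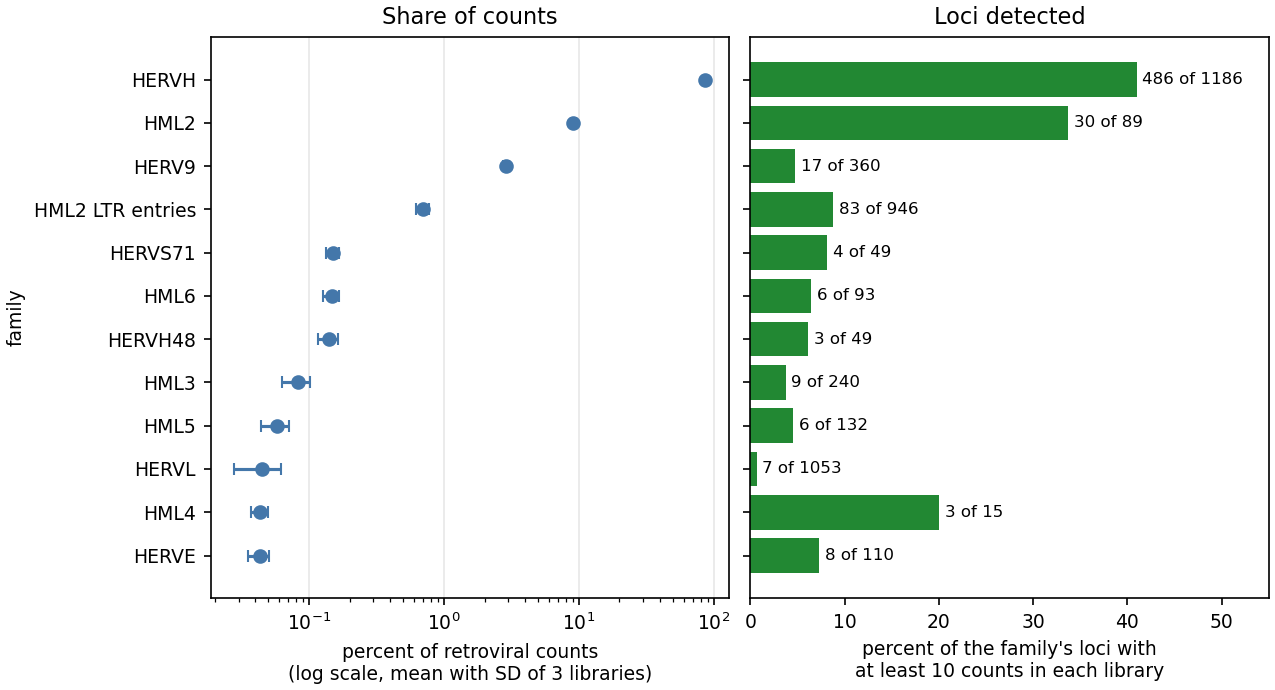
Left, percent of retroviral counts per family on a log axis, as the mean with SD of 3 libraries. Right, percent of each family's loci with at least 10 counts in each library, for the 12 families with the most counts. HERV-H and HML-2 lead on both measures, with 486 of 1186 and 30 of 89 loci detected.

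The share of loci detected was higher in HML-2 than in most families. Of the 89 HML-2 proviruses 33.7% were detected, against 579 of the 4450 proviral loci of all other families (odds ratio 3.40, 2-sided Fisher's exact test, p = 6.37e-07, adjusted p = 7.97e-07). Among the other HERV-K groups HML-1, HML-3, HML-4, HML-5 and HML-6 together, 25 of 564 loci were detected (odds ratio 10.96 for HML-2, Fisher's exact test, adjusted p = 5.58e-14). Of the HML-2 LTR entries 83 of 946 were detected (odds ratio 5.29, Fisher's exact test, adjusted p = 1.48e-09). The floor takes no account of length, and the median length was 972 bases in LTR entries against 7289 in HML-2 proviral rows. Whether length accounts for that difference was not tested. HML-2 was not separated from HERV-H, where 41.0% of loci were detected (odds ratio 0.732, Fisher's exact test, p = 0.218). Without HERV-H, 93 of the 3264 loci of other families were detected. These 5 tests run across loci, which are not biological replicates, and the adjusted values are Benjamini-Hochberg over the 5.

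HML-2 counts were concentrated in few proviruses. HML2_5q33.3, the provirus known as HERV-K107, gave 29677 ± 3165 CPM (SD, n = 3) and 43.0% ± 4.89 (SD, n = 3) of all HML-2 counts. It lies on chromosome 5 from 156657705 to 156666885 on the minus strand, antisense to an intron of the protein-coding gene SGCD. The use of strand in the counting is not given, so reads of a host gene on the other strand cannot be told from those of an antisense locus. Its share was 48.0% in replicate 1 (95% Wilson interval 47.8 to 48.3), 38.2% in replicate 2 (38.0 to 38.5) and 42.6% in replicate 3 (42.4 to 42.9). The 6 most abundant proviruses held 92.5% ± 1.39 (SD, n = 3) of HML-2 counts and the first 20 held 99.6% ± 0.144 (SD, n = 3). Of the 89 proviral loci 27 had 0 counts in every library, and 32 had some counts without being detected. The 89 rows are not all separate places, since HML2_1p36.21c lies wholly inside the interval of HML2_1p36.21b.

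The loci ranked below HML2_5q33.3 were well under its level in every library. HML2_7p22.1a and HML2_7p22.1b, the tandem copies of HERV-K108 on chromosome 7, gave 9236 ± 519 CPM and 5068 ± 183 CPM (SD, n = 3). Their intervals run from 4582425 to 4591104 and from 4591030 to 4600400, so they share only 75 bases, and neither overlaps an annotated gene. Their separate counts are uncertain where reads could be assigned to either copy. HML2_1q22 (HERV-K102, chromosome 1, 155626665 to 155635845) gave 8399 ± 706 CPM (SD, n = 3) and lies in an intron of the unprocessed pseudogene AL353807.3. HML2_11q23.3 (chromosome 11, 118721014 to 118730174) gave 7901 ± 923 CPM (SD, n = 3), antisense to an intron of the non-coding gene AP002954.1. HML2_22q11.21 (HERV-K101, chromosome 22, 18938673 to 18947848) gave 3646 ± 496 CPM (SD, n = 3) and overlaps exons of AC007326.4, which is annotated as protein-coding. HML2_22q11.23 (chromosome 22, 23536061 to 23546900) gave 1402 ± 450 CPM (SD, n = 3). It overlaps exons of the long non-coding RNA PCAT14, which has a row of its own. Its level may therefore depend on how reads were divided between these rows. HML2_11q22.1 (HERV-K118, chromosome 11, 101695062 to 101704528), antisense to an intron of TRPC6, gave 668 ± 95.6 CPM (SD, n = 3).

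The first 8 proviruses ranked in the same order in every library. HML2_5q33.3 exceeded HML2_7p22.1a by 1.68 ± 0.23 on the log2 scale (SD, n = 3). HML2_7p22.1a exceeded HML2_1q22 by 0.14 ± 0.06 and HML2_1q22 exceeded HML2_11q23.3 by 0.09 ± 0.07 on that scale, small differences that had the same sign in 3 of 3 libraries. Between neighbours among the first 20 proviruses, 12 of 19 pairs were higher in every library with a mean log2 ratio above its SD. HML2_3q12.3 (488 ± 100 CPM) and HML2_19p12b (439 ± 57.6 CPM) were not separated by that rule, and neither were HML2_3q13.2 (224 ± 116.97 CPM) and HML2_6q14.1 (221 ± 55.7 CPM, SD, n = 3 throughout). The remaining loci of the first 20 were HML2_1p31.1 (366 ± 54.4 CPM), HML2_1q23.3 (293 ± 14.2 CPM), HML2_4q32.1 (261 ± 46.9 CPM), HML2_8p23.1a (173 ± 65.4 CPM), HML2_11q12.3 (124 ± 58.1 CPM), HML2_3q27.2 (83.9 ± 15.3 CPM), HML2_12q14.1 (76.3 ± 10.5 CPM) and HML2_8p22 (56.4 ± 15.8 CPM). A sign-flip permutation test over 3 libraries cannot go below p = 0.25, so none was used to rank loci.

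**Figure D2:**
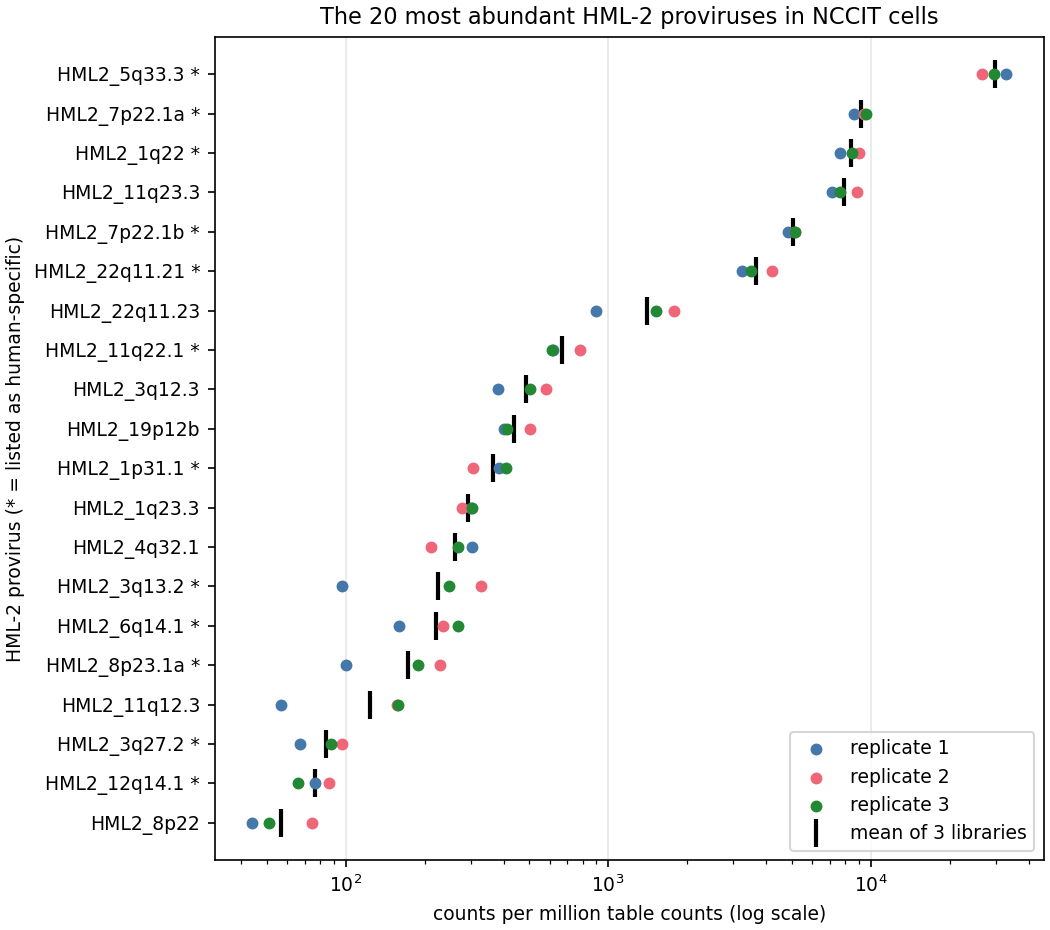
CPM, on a log axis, of the 20 most abundant HML-2 proviruses. Points are the 3 libraries, bars their mean, and asterisks mark loci listed as human-specific. HML2_5q33.3 stands apart from HML2_7p22.1a in every library, and the libraries spread most at HML2_3q13.2, where replicate 1 is lowest.

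Proviruses listed as human-specific, that is, absent from the genomes of other apes, were more abundant than the other HML-2 loci. Of the 16 HML-2 rows in the 12 bands listed as human-specific, 13 were detected, against 17 of the other 73 (odds ratio 14.3, 2-sided Fisher's exact test, p = 2.35e-05). The listed rows held 83.7% ± 2.19 (SD, n = 3) of HML-2 counts. Their median level was 223 CPM, against 0.299 CPM in the other HML-2 loci, which is under the limit that a count of 0 allows. On the log2(CPM + 0.5) scale the listed rows averaged 7.73 ± 4.74 and the others 1.44 ± 3.28 (SD across loci). This difference of 6.30 had p = 2e-05 in a 2-sided permutation test across loci, the smallest p that 100000 resamples can give. Over detected loci only, which leaves out the loci near the pseudocount, the difference was 2.98 (permutation test across loci, p = 0.0125). The list is not uniform. HML2_5p13.3 (HERV-K104) gave 19.5 ± 10.1 CPM (SD, n = 3), and 3 rows of band 8p23.1, HML2_8p23.1b, HML2_8p23.1c and HML2_8p23.1d, were not detected. These 3 entered because the band holds 4 HML-2 rows, of which only HML2_8p23.1a is at the position of HERV-K115. Young proviruses are near-identical in sequence, and counts of such copies are uncertain where reads can be assigned to more than 1 of them.

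HERV-H counts also came mostly from a small part of the family's loci. The first 8 of 1186 HERV-H loci made up 50% of the family's counts and 75 made up 90%, against 2 and 6 of the 89 loci in HML-2, so relative to family size HERV-H was not less concentrated. HERVH_3q13.2 was the most abundant retroviral locus at 76225 ± 955 CPM (SD, n = 3), on chromosome 3 from 112418411 to 112423365 with no annotated gene. HERVH_1q41h gave 60842 ± 2607 CPM, HERVH_12p13.32 56520 ± 1506 CPM and HERVH_16q21d 43176 ± 2964 CPM (SD, n = 3), the last 2 over exons of the long non-coding RNA genes AC007207.2 and AC009055.2. HERVH_3p14.3a gave 35522 ± 5785 CPM (SD, n = 3) and overlaps exons of ESRG, a non-coding transcript of human pluripotent cells. HERVH_6q22.1a (29312 ± 2949 CPM), HERVH_9q22.33c (23836 ± 2246 CPM), HERVH_1p32.3e (21518 ± 1116 CPM), HERVH_6q16.1b (18569 ± 1280 CPM) and HERVH_7q21.11 (18050 ± 262 CPM, SD, n = 3 throughout) completed the first 10 loci outside HML-2. HML2_5q33.3 was thus near HERVH_6q22.1a in mean CPM. These values are not divided by length, and the 2 rows span 9181 and 5930 bases.

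In the smaller families the share of counts in the first locus ranged widely, and the loci of 2 known placental envelope genes were not detected. HERVW_7q21.2, which holds the syncytin-1 gene ERVW-1, had 2, 0 and 3 counts, and HERVFRD_6p24.2, which holds the syncytin-2 gene ERVFRD-1, had 0, 2 and 2. HERV3_7q11.21, over exons of ERV3-1 and ZNF117, was detected at 56.0 ± 25.5 CPM (SD, n = 3). HERV9_12p13.31 gave 9844 ± 885 CPM (SD, n = 3), 44.6% of its family's counts. HERVS71_19q13.12a in LINC00665 (1079 ± 135 CPM), HERVH48_21q22.3 in ERVH48-1 (1030 ± 202 CPM) and HML6_19q13.43b in ERVK3-1 (965 ± 142 CPM, SD, n = 3 throughout) held 94.8%, 95.7% and 86.3% of their families' counts. The first locus held 38.6% in HERVL, 34.0% in HERVE, 23.4% in HML-3 and 10.4% in MER61.

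The first loci of the remaining proviral families reached at most 281 CPM on average. HML4_8q24.3 over exons of C8orf33 gave 281 ± 55.8 CPM, HML5_19q11 219 ± 29.4 CPM, HML3_5p15.33b 153 ± 67.3 CPM, HERVL_1q42.2 130 ± 46.0 CPM, HERVFRD_Xq21.33d 110 ± 29.5 CPM and HERVE_2q37.1 110 ± 13.8 CPM (SD, n = 3 throughout). Below 100 CPM were HERVW_4p13 (81.9 ± 22.06), HERVFC1_7q11.21 (79.4 ± 46.1), HERVI_3p25.1 (62.9 ± 29.9), HML1_19q13.43 (31.7 ± 18.6), PABLB_7q11.21 (31.0 ± 17.8), MER61_10q21.3 (21.1 ± 6.19), HERVK14C_1q44 (20.1 ± 8.98) and HERVFH21_11p15.4 (16.5 ± 8.11). No HERVL18 or HERVFC2 locus was detected. Of the HML-2 LTR entries, HML2.LTR499 was the most abundant at 1671 ± 372 CPM (SD, n = 3), on chromosome 9 from 121429105 to 121430073 in an intron of the non-coding gene AL359644.1.

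The replicates ranked the loci alike but differed by more than counting error. Across the 692 detected loci, which are not independent replicates, Pearson's r of log2 CPM was 0.982 to 0.992 and Spearman's rho 0.968 to 0.986 between pairs of libraries. A chi-square test of homogeneity with Benjamini-Hochberg adjustment, which sets libraries against counting error only, called 323 of the 692 loci varying, among them 24 of 30 HML-2 proviruses and 217 of 486 HERV-H loci. Without replicate 1, 195 of 772 detected loci varied, against 225 of 712 without replicate 2 and 282 of 704 without replicate 3. Each of these compares 1 library fewer, so they are not on the same footing as the 323. The coefficient of variation between replicates, from the common dispersion in edgeR, was 18.03% over all detected loci, 28.0% in HML-2 and 14.3% in HERV-H.

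Which replicate was lowest at the varying loci depended on the scaling. Replicate 1 was lowest at 209 of the 323 loci with CPM, and at 120 of 285 with DESeq2 size factors, whereas with TMM factors replicate 2 was lowest most often, at 122 of 298. Among HML-2 proviruses replicate 1 was lowest at 19 of 24 varying loci with CPM, 14 of 23 with DESeq2 size factors and 11 of 22 with TMM factors. Among the other proviral families without HERV-H it was lowest at 51 of 56, 40 of 49 and 39 of 49 loci. Among the HML-2 LTR entries it was lowest at 12 of 26, 9 of 33 and 8 of 34, and replicate 2 at 12, 19 and 22 of them. With retroviral totals, replicate 1 was lowest at 141 of 295 varying loci. These included 14 of 22 HML-2 proviruses, 44 of 52 loci of the other families without HERV-H and 10 of 31 LTR entries. HML2_3q13.2 had 211 counts in replicate 1 against 749 and 626 in replicates 2 and 3, and HML2_22q11.23 had 1966 against 4066 and 3862. Both were lowest in replicate 1 under the 3 scalings by CPM, DESeq2 and TMM. The overlapping PCAT14 row gave 1038, 1300 and 1462 CPM in replicates 1, 2 and 3, and HML2_22q11.23 gave 903, 1777 and 1526 CPM. How reads were divided between these rows is not given, so the size of the fall at HML2_22q11.23 is uncertain. HML2_5q33.3 had 71512, 60687 and 75088 counts and was highest in replicate 1 and lowest in replicate 2 under all 3 scalings. HML2_11q23.3 and HML2_22q11.21 completed the 5 HML-2 loci with the lowest adjusted p, with 15475, 20402 and 19440 and with 7038, 9603 and 8880 counts, and were lowest in replicate 1 except with TMM factors, where replicate 3 was lowest. Outside HML-2 the 5 loci with the lowest adjusted p were all HERV-H. HERVH_3p14.3a, HERVH_Xq21.33d and HERVH_Xq23l were lowest in replicate 1 under the 3 scalings and HERVH_6q22.1a under all but TMM, and HERVH_2q34d was highest there under all 3, with 1658 counts against 446 and 468. In replicate 1, the GAPDH row took 23.3% of all table counts, against 16.5% and 17.7% in replicates 2 and 3.

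**Figure D3:**
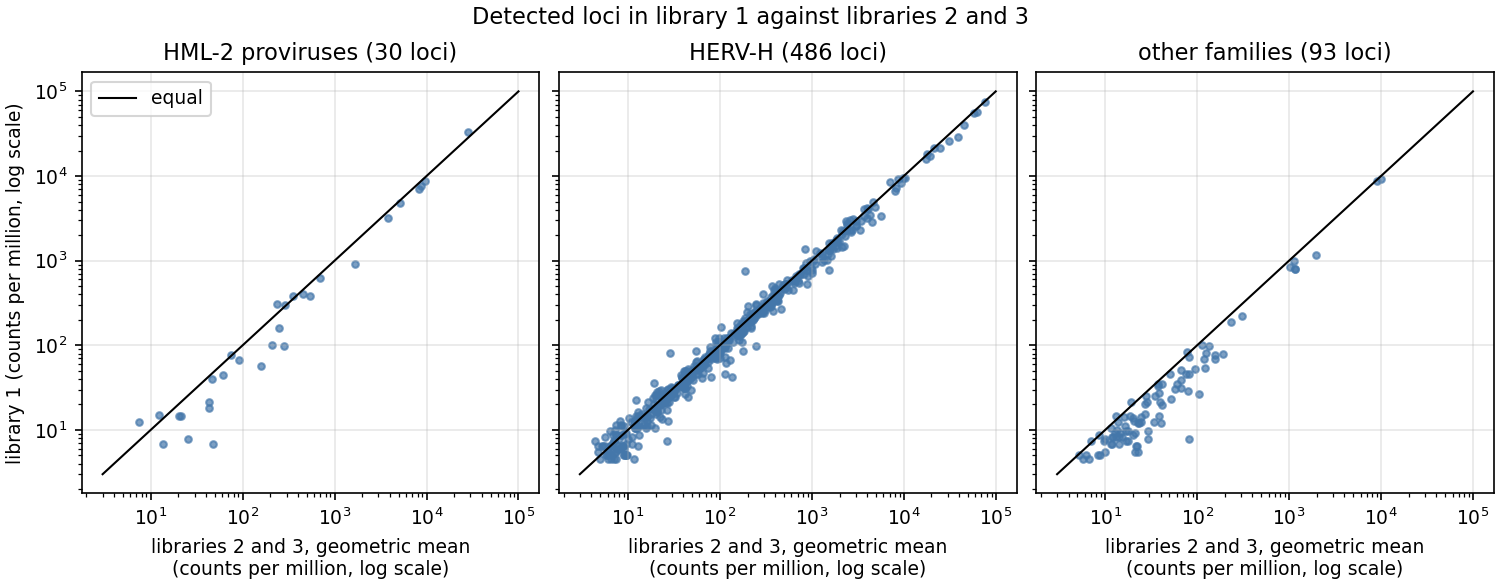
CPM in replicate 1 against the geometric mean of replicates 2 and 3, log axes, for detected HML-2 proviruses (30), HERV-H loci (486) and loci of other families (93). Points are loci and the line marks equal values. Points below the line are lower in replicate 1, which was the lowest library at 19 of the 24 varying HML-2 proviruses with this scaling and at 11 of 22 with TMM factors.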

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

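The tests on the concentration of HML-2 counts and on replicate 1 were chosen after the results were seen, as was the use of the interval's bound for the LTR entries, whose comparisons were set before. With no second group in the design, no biological explanation was tested for any pattern.

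Counts in 4 rows outside the comparisons lay above the limit that a count of 0 allows. GAPDH had a mean of 445021 counts per library. Its row runs from 6234517 to 6538371 on chromosome 12, over 23 annotated genes of which 11 are protein-coding. GENCODE places GAPDH from 6533927 to 6538374, so the ends nearly match and the starts do not. Whether reads were counted over the whole row, or its listed start is an error, is not known. ACTB had a mean of 103348 counts over a row with the bounds of 1 annotated transcript. GAPDH counts per ACTB count were 5.154, 3.998 and 3.841 in replicates 1, 2 and 3. PCAT14 had a mean of 2978 counts, and 95.6% of its row lies inside HML2_22q11.23, with a count ratio of 0.946 ± 0.209 (SD, n = 3). HML2.unk_lnc had a mean of 93.0 counts, and 83.8% of its row overlaps HML2_1q22, with a count ratio of 0.00477 ± 6.40e-04 (SD, n = 3). At that ratio, few reads of HML2_1q22 can have been counted in HML2.unk_lnc as well. How reads were otherwise divided between overlapping rows is not given in the sources used here.

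A few human-specific HML-2 proviruses held most HML-2 counts. The highest detected listed locus exceeded the lowest by at least 1029 times in each library. Reads shared evenly over all listed copies would leave their counts alike, so this ratio argues against such even sharing. It restates the pattern and so does not decide whether reads were shared unevenly, or between some of the near-identical copies. HML2_5q33.3 kept 41.9% of HML-2 counts per kilobase. This share could hardly move, since the 6 most abundant proviruses span 8680 to 9371 bases, so it does not decide on length. HML2_3q27.2 has the same 9181 bases as HML2_5q33.3 but gave 83.9 CPM against 29677, so length does not account for the difference between these loci. Whether ambiguous reads of 1 pool were assigned to a few copies cannot be told apart from unequal transcription: the highest share of the list total over the lowest between libraries had a median of 1.35 over the loci, but exceeded 1.5 at 5 of 13. Uneven transcription of these proviruses is a hypothesis that stays open, since read assignment was not given.

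Counts in HML-2 LTR entries may come from transcripts of host genes that run through them. Of the 165 entries on the sense strand of a gene 14 were detected, 1.04 times the share among entries overlapping no gene (95% interval 0.583 to 1.85, Fisher's exact test, p = 0.872). Entries only antisense to a gene, which counting without strand would raise, were detected 1.247 times as often (interval 0.785 to 1.98, Fisher's exact test, p = 0.350). Both intervals include 1 and reach well above it, so neither source can be told apart from transcription of the LTR itself. By counts, entries over sense exons held 2.82% and those in sense introns 37.3% of LTR counts, with 31.2% in HML2.LTR499 alone, against 42.4% in the 526 entries with no gene.

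Weaker HML-2 proviruses, with a mean of 10 to 1000 counts, were lower in replicate 1 by a median log2 shift of -0.65 over 25 loci, and of -0.45 with TMM factors. The shift was not uniform: 18 of the 25 were lower in replicate 1, and its quartiles were -1.47 and 0.03. Genomic DNA or another uniform background was first examined through the summed shift of other loci under 10 counts, -0.75 (95% interval -0.84 to -0.66), a test that came out in its favour but ignored how few counts these loci hold; in the density test that replaced it, 2037 loci with no gene accounted for 0.332% of the counts lacking. The ratio of weaker to abundant HML-2 counts in replicate 1 was 0.752 times that of the others (interval 0.725 to 0.780, counting error only). Abundant proviruses, with a mean of at least 1000 counts, shifted by a median of -0.19 (0.01 with TMM factors). The weaker ones differed from them by -0.46 (permutation test across loci, p = 0.0486). A fixed share of leaking reads would move both sets alike. These values rest on 1 library and a p near 0.05, so reads leaking from abundant proviruses stay open. Weak loci of other families shifted by a median of -0.79 (-0.58 with TMM factors), with no difference from weaker HML-2 proviruses detected (permutation test across loci, p = 0.291), while weak HERV-H loci shifted by -0.11, which turns to 0.09 with TMM factors, and weak HML-2 LTR entries by 0.05, or 0.25 with TMM (adjusted p = 1.2e-04 and 0.00219 against weaker HML-2 proviruses, permutation tests). A candidate explanation is a difference of replicate 1 shared by most weaker HML-2 proviruses and proviral loci of families other than HERV-H. The LTR entries did not share it, and whether it arose in the culture or the library was not tested.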

How the results depend on the processing

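Detection of HML-2 against other families, and the excess of human-specific proviruses, kept their direction and stayed past 0.05 under every alternative run, with odds ratios of 3.31 to 3.75 and log2 differences of 2.98 (detected loci only) to 8.13 (difference in medians). With loci of at least 8000 bases only, a setting chosen after seeing the data, that difference was 5.02 (permutation test, p = 0.00156). A floor of 1 count raised the detected loci from 692 to 1253. Counting LTR entries raised detected HML-2 loci from 30 to 113. The HML-2 share of retroviral counts moved from 9.08% to 10.1% without HERVH_3q13.2, to 5.66% per kilobase, to 9.77% with LTR entries and Rec rows, and to 5.37% without HML2_5q33.3. The value per kilobase rests on the same loci and counts, so it moved only through row length. The first HML-2 locus, HML2_5q33.3, spans 9181 bases and the first HERV-H locus, HERVH_3q13.2, spans 4955. The loci varying between replicates numbered 195 to 282 when 1 library was left out (195 without replicate 1, with fewer libraries compared), and 131 when a range above 1.5 times was also asked for. Scaling with TMM, DESeq2 or retroviral totals gave 298, 285 and 295 against 323. The coefficient of variation was 20.8% with DESeq2 and 12.2% without replicate 1. Leaving 1 of 3 libraries out cannot move a mean by more than the SD, so it says nothing about the stability of shares or of the 65 named loci, and TMM moved none of these by more than the SD. Settings added after seeing the data were those on LTR entries, length, single loci, retroviral totals and the 1.5-fold range. No paired analysis was possible because the study has 1 group. Depth limits the loci under 10 counts, of which a count of 0 allows up to 3.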

Other observations

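Where counts fell relative to annotated genes was described without a test between families. Of the HERV-H counts, 25.4% ± 0.809 (SD, n = 3) fell on loci over exons of annotated genes of the same strand and 54.3% ± 1.15 on loci with no annotated gene. HML-2 counts fell mostly on loci only antisense to genes (57.1% ± 3.24), most of them on HML2_5q33.3 with 43.0% of HML-2 counts, and 7.87% ± 1.30 on loci over sense exons. By number, 6 of the 30 detected HML-2 proviruses and 53 of the 486 detected HERV-H loci lay over sense exons, so the order of the families by loci is not that by counts. HERVH_18q21.31b, which overlaps the long non-coding RNA gene LINC-ROR on chromosome 18, gave 929 ± 139 CPM (SD, n = 3). After HML2.LTR499, the most abundant LTR entries were HML2.LTR517 on chromosome 10 at 552 ± 109.2 CPM and HML2.LTR495 on chromosome 9 at 437 ± 62.5 CPM (SD, n = 3), neither with an annotated gene. These loci were chosen after their values were seen.

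Among loci with at least 100 counts in some library, HML2.LTR809 had the highest ratio of its highest library to the mean of the others, a ranking that does not cover loci with 1 low library. It had 333 counts in replicate 1 and 2 in each of the others, on chromosome 19 from 48889635 to 48890598, antisense to an intron of TULP2. The next by this ratio was HERVH_2q34d, 4.01 times higher in replicate 1 than the mean of the others.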
